A study of Homo sapiens with 6 samples.

How the data were processed

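FoxO1 ChIP libraries (3) and Input libraries (3) from human primary chondrocytes of different donors were sequenced. Per the labels' protocols, chondrocytes were cross-linked close to confluence, FoxO1-bound DNA was isolated with an antibody, and libraries were made with an NEB Ultra DNA kit. Reads were aligned with Bowtie2 to hg19, per the submitters' processing notes, which give no version. The deposited file is 1 headerless peak list for the whole series. Its own name refers to PePr, a peak caller that models replicate libraries jointly, and to a cut-off written 1e3. The name also holds the words No-Blacklist and passed. It does not settle whether blacklisted regions were removed or no blacklist was applied. The settings of the peak caller and of its filters are not given in the sources used here. The list has 0 columns per library, so replicates could not be compared, and read depth is unknown.

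The authors' deposited fold per peak is a ratio of FoxO1 ChIP over Input on a linear scale. The scaling behind it is not stated. The authors' deposited p-value per peak was under 0.001 throughout, and the deposited adjusted p-value (q-value) was never below it. A deposited score column was the fold multiplied by 1 constant and was used only for that check. Peak names carry a number that follows the order of p, up to 5459. Of these numbers, 515 (9.43%) belong to no peak in the set analysed here, 39 of them among the first 500. Peaks on chromosomes 1 to 22 and X were kept. Statements on chromosomes, bands and clusters use the autosomes only. A fold reported for a peak or cluster is the authors' value and was used to describe and rank peaks within this list.

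No hg19 sequence or gene annotation was used here, since the gene table at hand describes assembly GRCh38.p14 and coordinates were not converted between builds. The planned analyses of promoters, exons and introns, of FOXO and other motifs, and of gene lists (FoxO targets, circadian clock, cartilage matrix, autophagy and others) were therefore not run, and peaks are named by position under the rule fixed before the data were examined: the 15 peaks with the smallest p, by coordinates only. The peaks with the highest fold and the clusters were chosen after their values were seen. The peak count and its stricter threshold were planned before the data were examined, and the analyses of bands, autosomes and clusters were added afterwards.

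Bands and autosome lengths came from the hg19 cytogenetic band table in the R package circlize 0.4.16 (R 4.3.3); 0 autosomal peaks ended past their chromosome. Peak centres were assigned to bands, and positions are printed counting from 1. Densities were counted over unstained bands and the 4 staining classes. Bootstrap intervals resampled the 22 autosomes 10000 times. The staining ratio was tested by joining these bands end to end on each autosome and rotating all of its peaks by a random distance 10000 times. Autosome densities were compared by shuffling 1-Mb bins between autosomes 10000 times. Neighbouring bins are not fully independent, so 5-Mb bins were an alternative. Clustering was tested by placing each peak at random in its own band 1000 times, with fewer placements for the alternative settings. Assembly gaps inside bands and differences in mappability were not modelled. Shares carry Wilson 95% intervals. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

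The 3 tests were checked on 4926 simulated peaks. With evenly placed peaks, the staining ratio was 0.948 (permutation p = 0.270), pairs within 10 kb were 0.938 times the expected number, and 0 autosomes were called. A planted ratio of 2 was recovered as 1.96, 20 planted clusters as 21, and 1 autosome planted at 2 times the density of the others was called. Simulated peaks were independent apart from the planted clusters, so these runs did not test the bin shuffle where neighbouring bins are alike. Alternatives were the stricter threshold (p at or under 1e-05), the 2463 autosomal peaks with the smallest p, merging of peaks closer than 1 kb, 1 peak per 100 kb, each autosome left out, 5-Mb bins, densities relative to band staining, placement over the whole autosome, a cluster gap of 20 kb, and removal of peaks within 2 Mb of a centromeric or variable band. Merging was applied to the peak count only.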

Results

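FoxO1 binding to DNA was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in human primary chondrocytes, the cells of articular cartilage. FoxO1 is a forkhead transcription factor that is held in the cytoplasm by insulin and PI3K signalling and otherwise acts in the nucleus. The design held 3 FoxO1 ChIP libraries, each from a different donor, and 3 Input libraries, which are sheared chromatin sequenced without immunoprecipitation and serve as the background. The question was where in the chondrocyte genome FoxO1 sits. The deposited result was 1 list of peaks for all 6 libraries together, with a fold enrichment of ChIP over Input, a p-value and an adjusted p-value per peak, all of them the authors' own. The list had no value per library, so no statement below carries a donor-to-donor error, and the sequencing depth of the libraries was unknown. Every interval computed here describes the spread between peaks, bins or autosomes within this single list. Permutation p-values compare the list with randomly moved peaks or shuffled bins, and the other p-values compare counts within it.

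FoxO1 peaks were short and were found on every autosome. The authors' deposited list held 4944 peaks on chromosomes 1 to 22 and X, 4926 of them on autosomes, which together covered 1265 kb. The median peak was enriched 8.16-fold over Input, with quartiles of 6.65 and 10.1 and a range of 1.90 to 29.4. Peaks were between 180 and 720 bp wide, with a median of 270 bp, and every width was a multiple of 90 bp. The median distance from one autosomal peak to the next was 208.6 kb.

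The peaks differed widely in how firmly they were separated from Input. All had an unadjusted p under 0.001, but 542 of the 4944 (11.0%) had an adjusted p under 0.05 in the authors' deposited table. The adjusted p was under 0.25 for 1282 peaks and equal to 1 for 1699 (34.4%). An unadjusted p at or under 1e-05 was reached by 828 peaks. The 542 peaks past the adjusted threshold had a median fold of 11.8 (quartiles 9.75 and 14.6), against 7.91 (quartiles 6.51 and 9.53) for the rest. The share passing rose with width up to 450 bp: none of the 2152 peaks of 180 bp passed the adjusted threshold (Wilson 95% upper limit 0.178%), compared with 3.05% of the 1739 peaks of 270 bp (2.34 to 3.97%), 41.7% of the 799 of 360 bp (38.3 to 45.1%) and 61.0% of the 200 of 450 bp (54.1 to 67.5%). Their median fold was 7.48, 8.17, 9.83 and 11.0 in the same order. Wider peaks were few and did not continue the rise in fold: the median was 9.37 for the 35 peaks of 540 bp and 9.21 for the 18 of 630 bp, of which 62.9% (46.3 to 76.8%) and 66.7% (43.8 to 83.7%) passed, and the single peak of 720 bp had a fold of 10.0 and did not pass. These intervals cover counting error only. Width and p came from the same peak calling, so their link is no independent evidence of peak quality.

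The 15 peaks with the smallest p lay on 11 different autosomes, were 360 to 630 bp wide and were enriched 10.3-fold to 25.1-fold (median 16.4-fold), with an adjusted p of at most 4.52e-05. Positions are given in hg19 coordinates, the build named in the submitters' processing notes. The strongest peak of the list was on chromosome 1 at 144989371 to 144989820 (band q21.1), enriched 18.8-fold with an adjusted p of 5.85e-20 in the authors' deposited table. The third strongest lay in the same band, at 145032391 to 145032840, with a fold of 10.3 and an adjusted p of 1.72e-06. The second was on chromosome 5 at 136806211 to 136806840 (q31.2), with a fold of 12.9 and an adjusted p of 4.08e-07. The fourth, on chromosome 15 at 39916891 to 39917340 (q14), had the highest fold of the 15, 25.1, with an adjusted p of 2.78e-06. The next places were taken by chromosome 17 at 76929391 to 76929840 (q25.3, 16.9-fold), chromosome 5 at 173250991 to 173251620 (q35.2, 21.1-fold) and chromosome 20 at 47545381 to 47546010 (q13.13, 12.7-fold). They were followed by chromosome 1 at 222886531 to 222886980 (q41, 13.3-fold), chromosome 7 at 27702541 to 27702990 (p15.2, 16.4-fold) and chromosome 6 at 45413551 to 45414000 (p21.1, 18.9-fold). The last 5 were on chromosomes 19 at 50316751 to 50317200, 3 at 16101631 to 16102170, 9 at 136009081 to 136009530, 12 at 31061701 to 31062060 and 17 at 41043511 to 41043960, with folds between 13.6 and 19.3. By fold alone the list was led by chromosome 6 at 143268571 to 143268930 (q24.2, 29.4-fold, adjusted p of 3.20e-04 in the authors' deposited table) and chromosome 15 at 93352411 to 93352770 (q26.1, 27.8-fold, adjusted p of 2.90e-04). The genes, exons and introns at these positions were not analysed here.

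FoxO1 peaks were concentrated in the Giemsa-light parts of the chromosomes, which are in general richer in genes than the dark bands. Unstained bands held 2704 peaks, or 2.21 per Mb (95% bootstrap interval over the 22 autosomes 2.02 to 2.40). The density was 2.25 per Mb in bands of the 25% staining class (1.91 to 2.61), 1.74 at 50% (1.59 to 1.91), 1.57 at 75% (1.39 to 1.79) and 0.950 in the darkest bands (0.772 to 1.15, 438 peaks). The ratio of unstained to darkest bands was 2.33 (1.91 to 2.83). Rotating the whole pattern of peaks along each autosome, which keeps the spacing of peaks, gave ratios of 0.916 to 1.23 in 95% of 10000 rotations and 1.39 at most (two-sided permutation p = 0.0002, the smallest these rotations can give). The unstained bands were the denser ones on 17 of the 17 autosomes that have both classes (exact sign test, two-sided, p = 1.53e-05). The ratio was 2.81 among the 542 peaks with an adjusted p under 0.05 and 2.28 among the other autosomal peaks. The odds ratio between these sets was 1.23, which did not pass Fisher's exact test (two-sided, p = 0.254). Centromeric, variable and stalk bands, which span 219.4 Mb in hg19, held 39 peaks and were left out of these densities.

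**Figure D1:**
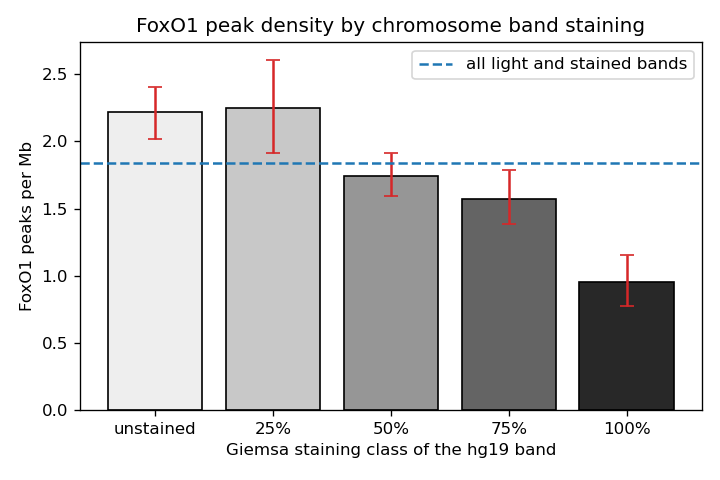
FoxO1 peaks per Mb (vertical axis) by Giemsa staining class of the hg19 band (horizontal axis), over the 22 autosomes; bars are densities, red error bars are 95% bootstrap intervals over autosomes, and the dashed line is the density over all light and stained bands, 1.84 per Mb. Density was 2.21 per Mb in unstained bands and 0.950 per Mb in the darkest bands.

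Among the autosomes, chromosome 17 had the highest density of FoxO1 peaks and chromosomes 13 and 4 the lowest. In 1-Mb bins of the light and stained bands the mean was 2.70 ± 0.252 peaks per Mb on chromosome 17 (SE over 77 bins), 1.20 ± 0.112 on chromosome 4 (186 bins) and 1.07 ± 0.141 on chromosome 13 (95 bins), against 1.84 per Mb overall. Shuffling bins between autosomes 10000 times gave two-sided permutation p-values, adjusted by Benjamini-Hochberg over 22 autosomes, of 0.0088 for chromosome 17, 0.0044 for chromosome 4 and 0.0044 for chromosome 13. None of the other 19 autosomes passed, and 2 of them, chromosomes 10 and 18, had an unadjusted p under 0.05 (0.0226 and 0.0498). With the density expected from each autosome's band staining taken into account, chromosome 17 held 1.36 times the expected number (adjusted permutation p = 0.0293), chromosome 4 held 0.675 times (0.0044) and chromosome 13 held 0.618 times (0.0044). Chromosome 19, the most gene-dense human chromosome, held 2.17 ± 0.268 peaks per Mb (SE, 46 bins), 0.975 times the number expected from its bands (adjusted permutation p = 0.982). Chromosome 17 held 1.47 times the average density in 1-Mb bins. Its call was lost in 5-Mb bins (1.46 times, adjusted permutation p = 0.0601), in the 2463 autosomal peaks with the smallest p (1.41 times, 0.122) and at a p at or under 1e-05 (1.47 times, 0.183), with little change in size. The calls for chromosomes 4 and 13 passed in all 3 settings, and at a p at or under 1e-05 their densities were 0.434 and 0.442 times the average, against 0.652 and 0.584 for all peaks.

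**Figure D2:**
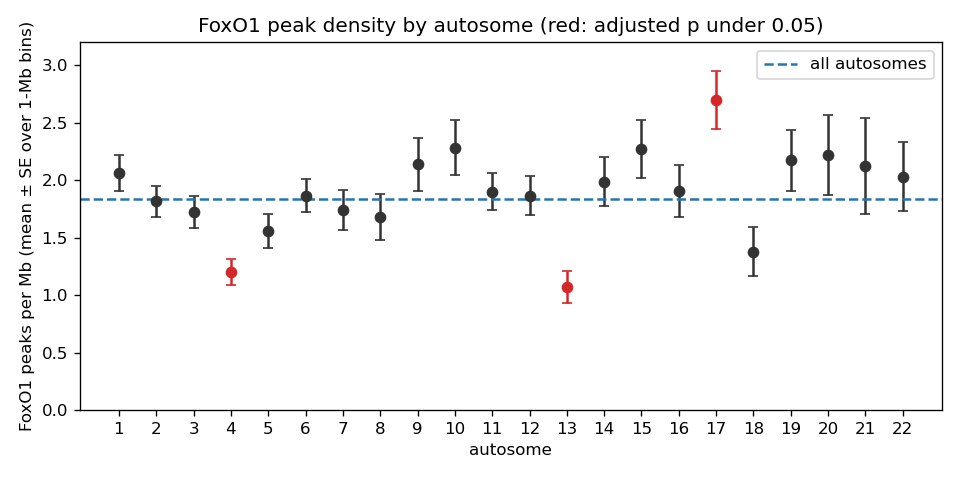
Mean FoxO1 peaks per Mb (vertical axis) on each autosome (horizontal axis); points are means over 1-Mb bins, error bars are SE over bins, red points have an adjusted permutation p under 0.05, and the dashed line is the overall density, 1.84 per Mb. Chromosome 17 lies at 2.70, and chromosomes 4 and 13 lie at 1.20 and 1.07.

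FoxO1 peaks also lay in clusters. On the autosomes, 413 neighbouring pairs were separated by less than 10 kb, 3.33 times the 124 found on average when every peak was placed at random within its own band (95% range 104 to 145, two-sided permutation p = 0.002, the smallest that 1000 placements can give). In the full list 94 neighbouring pairs lay within 1 kb, and these were not merged for the tests of pairs and clusters. There were 27 clusters of 5 or more peaks with successive gaps of at most 50 kb, holding 164 peaks. Random placement gave 1.92 such clusters on average and 8 at most (two-sided permutation p = 0.002, again the smallest possible). In 15 of the 27 clusters at least 1 peak had an adjusted p under 0.05. Of all peaks 11.0% passed, and the 15 were not compared with a number expected from that share. The largest cluster in any random placement held 10 peaks, and 1 of the 27, with 13 peaks, was larger. That cluster lay in a centromeric band. Its peaks were placed over the whole band, assembly gaps included, so this comparison cannot tell whether its size exceeds chance. Cluster size was not tested further. With gaps of at most 20 kb there were 9 clusters against 0.078 expected (two-sided permutation p = 0.004). The 2463 peaks with the smallest p gave 5 against 0.118 (0.004), and those with a p at or under 1e-05 gave 1 against 0.002 (0.008). These settings used fewer placements, and 0.004 was the smallest permutation p they could give. The 1 cluster at a p at or under 1e-05 lay around the strongest peak of the list, in q21.1 of chromosome 1. That band also held 7 peaks with a fold under 4.

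In 23 of the 27 clusters the median fold was between 4.69 and 12.4. Chromosome 1 at 8065351 to 8194230 (p36.23) held 10 peaks with a median fold of 7.25, and chromosome 2 at 204447241 to 204553980 (q33.2) held 7 with a median fold of 10.6. Around the strongest peak of the list, chromosome 1 at 144967141 to 145032840 (q21.1) held 7 peaks with a median fold of 8.08, 5 of them with an adjusted p under 0.05. On chromosome 5 at 150385681 to 150460920 (q33.1), 4 of 5 peaks passed the adjusted threshold, and the median fold was 10.3. The highest median fold of a cluster, 12.4, was on chromosome 15 at 50156011 to 50220090 (q21.2), where 3 of 5 peaks passed. Chromosome 1 at 203123341 to 203172120 (q32.1) held 5 peaks with a median fold of 11.2. Chromosome 3 at 11540611 to 11642220 (p25.3), chromosome 5 at 95582881 to 95674770 (q15), chromosome 9 at 4828861 to 4905180 (p24.1) and chromosome 11 at 36031141 to 36110340 (p13) held 6 peaks each, with median folds of 9.72, 7.90, 6.56 and 7.82. A further cluster of 6, on chromosome 4 at 190478881 to 190514430 (q35.2), had the lowest median fold of the 23, 4.69 (range 2.49 to 8.77), and none of its peaks passed the adjusted threshold.

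The other 4 clusters had a median fold under 4. The largest cluster of the list was one of them, with 13 peaks on chromosome 21 at 11033821 to 11183130 (p11.1), in a centromeric band, and a median fold of 3.07. The others were chromosome 8 at 86734081 to 86824170 (q21.2), with 9 peaks and a median fold of 2.73, chromosome 20 at 29580841 to 29653560 (q11.21), with 8 peaks and 2.39, and chromosome 9 at 68996161 to 69065730 (q21.11), with 5 peaks and 3.14. Of these 35 peaks, 2 had an adjusted p under 0.05 in the authors' deposited table.

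**Figure D3:**
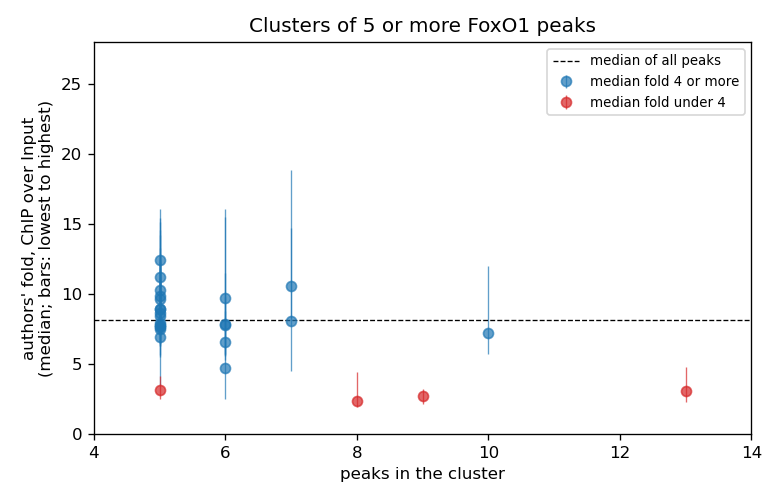
Median fold of ChIP over Input (vertical axis; bars run from the lowest to the highest fold in the cluster) against the number of peaks (horizontal axis) for the 27 autosomal clusters of 5 or more FoxO1 peaks; the dashed line is the median of all peaks, 8.16. The 4 clusters in red have a median fold between 2.39 and 3.14, and the 23 in blue lie between 4.69 and 12.4.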

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

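The size of the list depended on the threshold: 828 peaks had a p at or under 1e-05, against 4944 in the full list, and 4850 remained as separate peaks after those closer than 1 kb were merged. The ratio of unstained to darkest bands stayed past its test in each setting tried, at 2.66 with the stricter threshold, 2.48 in the 2463 strongest peaks, 2.18 with 1 peak per 100 kb, and between 2.26 and 2.49 with any of the 22 autosomes left out (two-sided permutation p = 0.001 each time, the smallest that 2000 rotations can give). Pairs within 10 kb were between 3.29 and 4.34 times the expected number. The number of clusters fell to 5 in the 2463 strongest peaks and to 1 with the stricter threshold, which hold fewer peaks, and to 9 with gaps of at most 20 kb, a tighter definition. Random placement fell too, to 0.118, 0.002 and 0.078 clusters on average, and each setting passed the permutation test. With the stricter threshold that result rests on the 1 cluster around the strongest peak, in q21.1 of chromosome 1. Without peaks within 2 Mb of centromeric or variable bands there were 25 clusters. The number of autosomes off the average density was 2 or 3 in each setting. Chromosome 17 did not pass in 5-Mb bins, in the 2463 strongest peaks, or with the stricter threshold (adjusted permutation p = 0.183), where its density was still 1.47 times the average, and the cause was not tested. No paired analysis was possible because the peak list holds no value per library, and for the same reason no replicate could be left out. Other settings for promoters, motifs, repeats and gene lists, listed before the data were examined, were not run, since no hg19 sequence or annotation was used. Depth per library is unknown and limits what can be said of the weaker peaks.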

Other observations

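The tests and comparisons in this part were chosen after the values were seen, with exceptions. These were the test of weak peaks lying near strong ones and the comparison, made without a test, of neighbours among low-fold peaks.

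The peaks with an adjusted p of 1 were 1699 in number, and the smallest unadjusted p among them was 3.70e-04. The adjusted p divided by p reached 17191543 for the strongest peak. If that is the number of genomic windows tested, chance alone would give about 17192 windows with p under 0.001, more than the peaks listed. A list made only of chance windows spread evenly over the genome is argued against by their position: the 1694 of these peaks on autosomes had a ratio of unstained to darkest bands of 2.29, above the 1.58 reached at most in 10000 rotations. They also lay near strong peaks more often than placement within the same bands gave, with 4.84% within 50 kb of a peak with an adjusted p under 0.05, against 2.61% expected (95% range 1.89 to 3.37%, two-sided permutation p = 0.002, the smallest possible). Weak FoxO1 sites beside strong ones, and background that follows accessible or easily sequenced chromatin in ChIP more than in Input, may both give this pattern and stay open. Both comparisons assume an even spread, along the autosome or within bands. Chance windows spread unevenly were therefore not tested and stay open too. Peaks closer than 1 kb were not merged before the count near strong peaks.

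The fall in peak density with band staining, a ratio of 2.33, is not accounted for by chance position along the chromosomes, since no rotated pattern exceeded 1.39. A bias of ChIP against Input with base composition is a candidate explanation, because light bands are richer in G and C. Chromosome 19 is among the richest in G and C, and held 0.975 ± 0.120 (SE) times the peaks expected from its bands, which does not decide the question. It was the only autosome set against this explanation. Chromosomes 4, 13 and 17 departed from the number expected from their bands (0.675, 0.618 and 1.36 times). Whether these departures follow base composition was not tested. Without the sequence, base composition cannot be told apart from a preference of FoxO1 for gene-rich or open chromatin, which was not tested.

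There were 100 autosomal peaks with a fold under 4, and 1 of them had an adjusted p under 0.05. They lay in 45 bands, 31 of which held 1 each, while 37 of the 100 lay in 4 bands (12 in p11.1 of chromosome 21, 11 in q21.2 of chromosome 8, and 7 each in q21.1 of chromosome 1 and q11.21 of chromosome 20). Of the 50 1-Mb bins with such a peak, 32.0% lay within 2 Mb of a centromeric, variable or stalk band, against 2.91% of the 1717 bins with other peaks only (Fisher's exact test, two-sided, p = 4.11e-12), as reads from repeated sequence beside centromeres, collapsed in the assembly and deep in Input, would predict. With a limit of 5 Mb the shares were 40.0% and 7.57% (p = 5.74e-10 in the same exact test), and with a fold under 3 they were 47.6% and 3.21% (exact p = 6.75e-10). These exact tests treat bins as independent, while neighbouring bins can share both traits. Of the 54 low-fold peaks away from those bands, 44.4% had another low-fold peak within 100 kb, against 71.7% of the 46 beside them, a difference that was not tested because neighbours share their status. Any peak lay within 100 kb of 66.7% of these 54, against 53.3% of the other peaks. Without Input depth it stays open whether repeats may account for them too. These peaks are the ones to look at first against the Input reads, together with the strongest peak of the list, which shares band q21.1 of chromosome 1 with 7 low-fold peaks.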
